A study of Homo sapiens with 9 samples.

How the data were processed

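The series holds 9 RNA-seq libraries of MDA-MB-231, an established triple-negative breast cancer line, from polyadenylated RNA (oligo-dT beads) sequenced on a BGISEQ-500. The titles give 3 groups of 3 libraries: shNC (negative control), shPDE3A_1 (set 1) and shPDE3A_2 (set 2). Nothing in the labels says that the 2 shPDE3A sets carry different hairpins, or that libraries of a group come from separate cultures, so p values here measure only the spread between these samples.

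The authors' tables, 1 per library, give for each gene an expected count and an FPKM value, per the file headers. The submitters' processing notes name HISAT2, Bowtie2, RSEM and the human assembly hg19. They give no versions, and the use of each tool is not stated per step. RSEM expected counts share reads that fit several genes, so values for close paralogs, read-through genes and genes with processed pseudogenes are less certain than others. The deposited tables list only genes of at least 0.01 FPKM, and a gene absent from a library was set to a count of 0. The 3056 genes absent from some library had a median highest count of 2. The libraries summed to 20.7 to 22.1 M expected counts per the deposited tables, so depth was close to even across groups.

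Expected counts from the deposited tables were rounded and fitted with edgeR 4.0.16 in R 4.3.3: quasi-likelihood tests on all 9 libraries with a term per group, TMM factors, and a low-count filter (filterByExpr, minimum count 10, minimum total 15) that kept 12599 of 16335 genes. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Set 1 and set 2 were each compared with shNC and with each other, and a gene was called in both sets when both calls had the same sign. Every adjusted p of a gene in the text is from this edgeR fit unless another tool is named.

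Gene lists, 26 in number, were fixed from textbook knowledge and tested with camera (limma 3.58.1, inter-gene correlation preset to 0.01) where at least 5 members were tested, 24 lists in all. The test with a correlation estimated per list stands beside it, and the calls that the rotation test fry changed are given with the processing alternatives. The mitochondrially encoded mRNAs, listed in no deposited table, and the Schlafen family, with 3 tested members, had no set test.

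Genes named in the text followed a rule: PDE3A, the 8 genes per direction changed most in both sets, the 3 per direction changed most in each set without overlap of the libraries and 3 per direction between the sets, each with a mean of at least 1 FPKM in a group, and up to 3 members of each list, in order of mean change. Other genes named were chosen after their values were seen, and the text says so. Some genes that the rule selects are not reported here. These groups, comparisons, lists, thresholds, the naming rule and the main alternatives were chosen before the data were examined.

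The alternatives were DESeq2 1.42.0 size factors in the same edgeR fit, no low-count filter, a floor of 1 FPKM, DESeq2 in full, fits of only the groups compared, the replicate number as a block, limma on log2 of the deposited FPKM plus 1 or 0.1, each library left out in turn, a 2-fold threshold, and both sets pooled as 6 libraries. Voom with a quality weight per group and the removal of each library's trend on GC content or on transcript length were added after the data were seen. GC content and length came from the human transcript annotation at hand (GRCh38, not the authors' hg19), which matched 99.2% of the genes. No genomic coordinates are given here, since the tables hold none.

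The analysis was tested on simulated counts with 200 changed genes. Of 2-fold changes 72.7 to 74.6% were recovered, of 3-fold changes 91.9 to 96.8%, and of 1.5-fold changes 21.2 to 32.8%. Genes simulated as unchanged but called numbered 11 in set 1 (7.91% of its calls) with pooled spread and 13 (9.22%) with spread simulated per group. In set 2 they numbered 5 (3.7%) and 0, and between the sets none was called. Since both sets share 3 controls, 20 draws with no change in either set were simulated, with 3 simulated controls shared by both. Protein, phosphodiesterase activity and cell behaviour were not analysed here.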

Results

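RNA-seq libraries of MDA-MB-231 breast cancer cells with a control hairpin (shNC) or 1 of 2 shPDE3A labels (set 1, set 2) were compared, with n = 3 libraries per group. Each library held 20.7 to 22.1 M expected counts and listed 14538 to 14760 genes, and 12599 genes were tested. Gene changes are log2 fold changes ± standard error from edgeR with adjusted p values, and list changes are mean log2 fold changes with adjusted p values from camera. The standard error was derived as the absolute log2 fold change over the square root of the quasi-likelihood F statistic. It rests on 1 spread per gene shared by all groups, so it does not show the spread of each set. A result "without" a library is from a fit that leaves out that 1 library, and "without any" of several means each left out in turn. Set 1 libraries differed more from each other than those of other groups, with a coefficient of variation of 22.4% against 6.9% in shNC and 9.22% in set 2.

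PDE3A, the cyclic nucleotide phosphodiesterase for which the hairpins are named, was close to the detection limit in every library, controls included. Its expected counts were 0, 1 and 3.03 in shNC libraries 1 to 3, 2.01, 0 and 0.86 in set 1, and 3.01, 2 and 4 in set 2, or 0 to 0.03 FPKM. The pooled ratio to shNC was 0.759 in set 1 (95% interval 0.111 to 4.48, exact Poisson p = 1) and 2.3 in set 2 (0.642 to 10.2, exact Poisson p = 0.175). These intervals and p values cover counting error only, on summed expected counts, and leave out the spread between libraries. PDE3A did not pass the count filter, and in a fit without a filter it stood at -0.23 ± 1.21 in set 1 (adjusted p = 0.939) and 1.17 ± 1.0 in set 2 (adjusted p = 0.737). The knockdown can therefore not be measured from these counts.

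**Figure D1:**
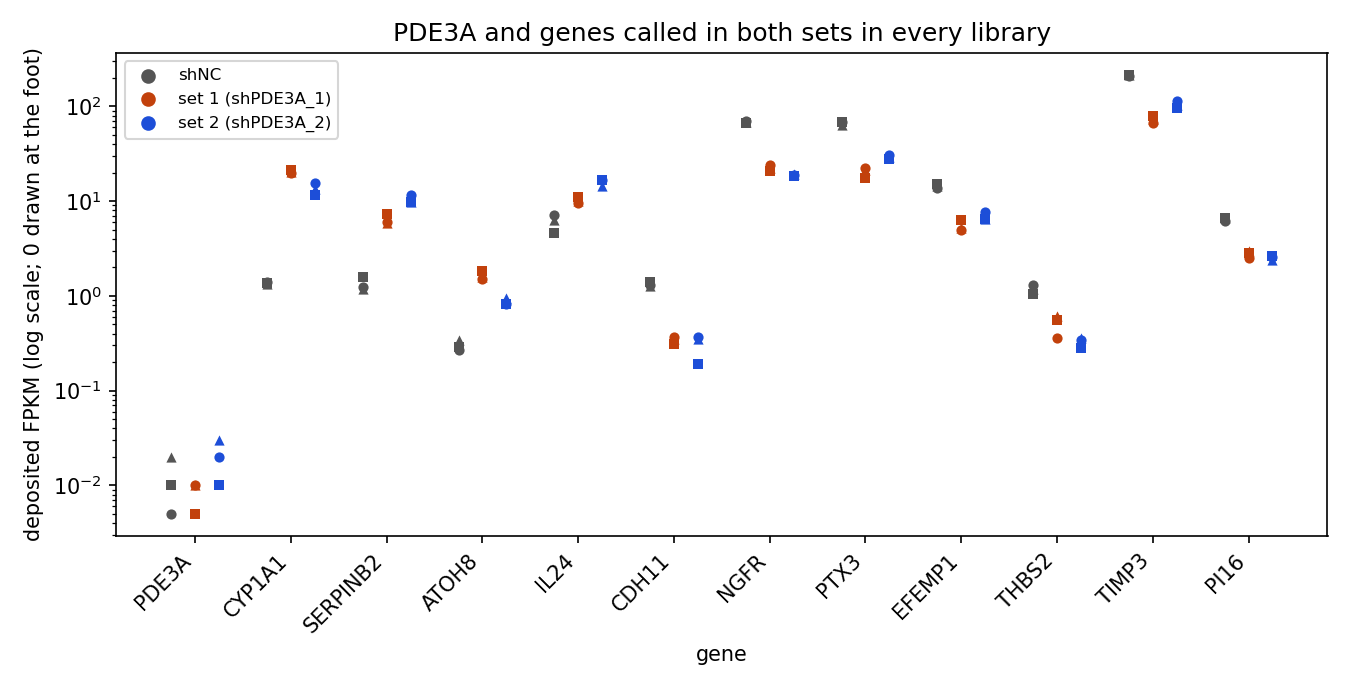
PDE3A and 11 genes called in both shPDE3A sets, in each of the 9 libraries. The vertical axis gives FPKM as deposited on a log scale, with a value of 0 drawn at the foot. Each point is 1 library, coloured by group, with the marker giving the library number within its group.

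Of 15 other cyclic nucleotide phosphodiesterases tested, 3 fell in set 1 and 0 in set 2 (edgeR, with 1 member called, higher, when set 2 and shNC were fitted alone). PDE8A fell by 0.72 ± 0.15 (adjusted p = 0.00709). PDE4B stood at -1.06 ± 0.27 (adjusted p = 0.016) and PDE7A at -0.71 ± 0.17 (adjusted p = 0.0105). PDE4B lost its call without shNC library 1 or 3 (adjusted p up to 0.0724) and PDE7A without shNC library 3 or set 1 library 3 (adjusted p up to 0.0532), and without shNC library 3 only PDE8A of the 3 was called. Neither PDE4B (adjusted p = 0.0827) nor PDE7A (0.0665) was called with the GC trend removed. The list as a whole was at -0.24 in set 1 (adjusted p = 0.415) and at a mean of 0.02 and median of -0.04 in set 2, with the test pointing down (adjusted p = 0.948). Among 29 components of cAMP signalling, 3 rose and 7 fell in set 1 (list adjusted p = 0.47), and PTGER4, the prostaglandin E receptor EP4, fell by 1.56 ± 0.30 (adjusted p = 0.00444). Without set 1 library 3 or shNC library 1 or 3 the list had 1 higher and 2 lower members, and without set 1 library 2 it had 3 and 11. CREM, a cAMP-responsive transcription factor, stood at 0.56 ± 0.14 (adjusted p = 0.0135, 0.0658 without shNC library 3). AKAP12, an anchor of protein kinase A, stood at -0.72 ± 0.19 (adjusted p = 0.0181, up to 0.0738 without shNC library 1 or 3 or set 1 library 3, and 0.122 with the GC trend removed). Of 27 CREB target genes 6 rose and 4 fell in set 1 (mean 0.07, median 0.20, adjusted p = 0.47). The immediate early genes EGR1 and ATF3 rose by 1.78 ± 0.30 (adjusted p = 0.00283) and 1.28 ± 0.20 (adjusted p = 0.00235). The small GTPase gene GEM stood at -0.91 ± 0.20 (adjusted p = 0.00799). Without shNC library 1 the CREB list had 5 higher and 1 lower members, and without shNC library 3 it had 4 and 2. In set 2 none of the cAMP or CREB members was called, and the lists stood at -0.05 (adjusted p = 0.464) and -0.08 (adjusted p = 0.495). The fit of set 2 and shNC alone called 1 higher and 3 lower cAMP members, and 3 higher and 2 lower CREB members.

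In set 1 against shNC, target genes of ATF4, the transcription factor of the amino acid and integrated stress response, rose as a group, and genes of mitosis fell. Of 33 ATF4 target genes 23 rose, 0 fell and 10 did not pass (mean 1.13, adjusted p = 1.99e-13, and adjusted p = 0.496 with an estimated correlation). CHAC1, an enzyme that degrades glutathione, rose by 2.65 ± 0.36 (adjusted p = 0.00139). SESN2, a leucine sensor upstream of mTORC1, rose by 2.47 ± 0.35 (adjusted p = 0.00166). NUPR1, a stress-induced chromatin protein, rose by 3.57 ± 0.72 (adjusted p = 0.00545), from 5.40 ± 1.38 to 59.1 ± 53.3 FPKM (mean ± SD). Its change was 2.71 without set 1 library 2, and set 1 library 1 (6.58 FPKM) lay within the shNC range of 3.9 to 6.62. Adjusted over the list alone, 27 members were higher. The level of the list over shNC was uneven within set 1, at 0.31, 1.57 and 1.12 in libraries 1, 2 and 3, and at 0.02, 0.00 and 0.03 in the set 2 libraries.

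Of 39 genes of G2/M and mitosis, 25 fell, 0 rose and 14 did not pass in set 1 (mean -0.55, adjusted p = 2.34e-15, and adjusted p = 0.496 with an estimated correlation), with the same 25 adjusted over the list alone. CENPF, a kinetochore protein, stood at -0.98 ± 0.10 (adjusted p = 0.000639). ASPM, a spindle pole protein, stood at -0.99 ± 0.10 (adjusted p = 0.000639) and the proliferation marker MKI67 at -0.87 ± 0.12 (adjusted p = 0.00155). All 3 were called whichever library was left out. The list level was -0.28, -0.85 and -0.59 in set 1 libraries 1 to 3. With each library's GC trend removed 14 members were lower. Of 36 genes of G1/S and DNA replication 15 fell, 0 rose and 21 did not pass (mean -0.27, adjusted p = 0.000825, and adjusted p = 0.558 with an estimated correlation). Of G1/S genes 17 were lower adjusted over the list alone. TYMS, thymidylate synthase, stood at -0.68 ± 0.14 (adjusted p = 0.00548). The replication genes MCM10 (-0.76 ± 0.21, adjusted p = 0.0191) and CLSPN (-0.69 ± 0.21, adjusted p = 0.0315) lost their calls without shNC library 1 or 2 or set 1 library 3. CLSPN also lost it without shNC library 3 or set 2 library 2 (adjusted p up to 0.071 for MCM10 and 0.115 for CLSPN). Neither was called with the GC trend removed (adjusted p = 0.203 and 0.248). The G1/S level was 0.02, -0.63 and -0.31 in set 1 libraries 1 to 3. Lower members numbered 26 without set 1 library 1, 7 without library 3 and 8 without shNC library 1, 2 or 3. Without set 1 library 2, 5 were higher and 16 lower and the list call was lost (adjusted p = 0.177). The G1/S shift relative to other genes was then -0.11 against -0.29. With the GC trend removed 3 were lower.

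Target genes of the transcriptional coactivators YAP and TAZ fell in set 1, 14 of 28 lower, 0 higher and 14 not passing (mean -0.40, adjusted p = 2.45e-06, and adjusted p = 0.496 with an estimated correlation). For YAP/TAZ 15 were lower adjusted over the list alone. NUAK2, a kinase acting on the actin cytoskeleton, fell by 1.24 ± 0.16 (adjusted p = 0.0011). SDPR, a caveola protein, fell by 1.11 ± 0.21 (adjusted p = 0.00436) and EDN1, endothelin 1, by 0.94 ± 0.21 (adjusted p = 0.0092). The YAP/TAZ level was -0.21, -0.67 and -0.41 in set 1 libraries 1 to 3. Of 31 collagens and matrix glycoproteins 13 fell, 1 rose and 17 did not pass (mean -0.46, adjusted p = 1.77e-06, and adjusted p = 0.496 with an estimated correlation). Matrix members called adjusted over the list alone were 14. The fibulin EFEMP1 fell by 1.25 ± 0.11 (adjusted p = 0.000248). The laminin chain LAMA5 fell by 1.13 ± 0.11 (adjusted p = 0.000345) and the thrombospondin THBS2 by 1.05 ± 0.20 (adjusted p = 0.00441). The matrix level was even across set 1, at -0.47, -0.57 and -0.42. Without set 1 library 1 the matrix list had 3 higher and 17 lower members. These calls of YAP/TAZ and matrix genes held without any 1 library, but EDN1 was not called with the GC trend removed (-0.70, adjusted p = 0.0758).

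Genes of cholesterol synthesis and uptake rose in set 1, 8 of 30 higher, 0 lower and 22 not passing (mean 0.50, adjusted p = 0.000241, and adjusted p = 0.558 with an estimated correlation). As many cholesterol genes, 8, were higher adjusted over the list alone. The sterol reductase TM7SF2 rose by 1.17 ± 0.15 (adjusted p = 0.00126) and the kinase PMVK by 0.70 ± 0.14 (adjusted p = 0.00558). The list level was -0.31, 0.94 and 0.51 in set 1 libraries 1 to 3. Without set 1 library 1, 24 members were higher, and 5 without set 1 library 3 or shNC library 1, 2 or 3. Cholesterol genes were not called as a list without set 1 library 2 (adjusted p = 0.0706), where their shift relative to other genes was 0.21 against 0.49. Hypoxia and glycolysis genes rose in 9 and fell in 2 of 39 cases, and 28 did not pass (mean 0.47, adjusted p = 0.00284, and adjusted p = 0.558 with an estimated correlation). ANGPTL4, a lipase inhibitor, stood at 2.86 ± 0.73 (adjusted p = 0.015). The stress-responsive NDRG1 stood at 1.58 ± 0.53 (adjusted p = 0.0431) and the peptide hormone ADM at 1.09 ± 0.26 (adjusted p = 0.0119). At 1.86 without set 1 library 1, ANGPTL4 was at 11.19, 0.88 and 5.04 FPKM in set 1 libraries 1 to 3 and 0.84 to 0.92 in shNC, an order opposite to that of the list. ANGPTL4 lost its call without any of the 3 shNC libraries (adjusted p up to 0.0588) or with limma on FPKM (0.0519), and ADM without shNC library 2 (0.0533). NDRG1 lost it in every fit but those without set 1 library 1 or set 2 library 1 (up to 0.126), and stood at 0.95 without set 1 library 2. NDRG1 (adjusted p = 0.113) and ADM (0.0581) were not called with the GC trend removed. The hypoxia level was 0.01, 0.66 and 0.44 in set 1 and -0.17, 0.37 and 0.23 in set 2. Its higher and lower members numbered 23 and 2 without set 1 library 1, and 4 and 0 without set 1 library 3 or shNC library 2. They were 2 and 1 without shNC library 1, 2 and 0 without shNC library 3, and 7 and 1 without set 2 library 2 or 3.

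Cytosolic ribosomal protein genes rose in set 1, 43 of 78 higher, 0 lower and 35 not passing (mean 0.40, adjusted p = 4.71e-13, and adjusted p = 0.558 with an estimated correlation). Adjusted over the list alone 47 were higher, though reads of these genes also fit their pseudogenes. RPLP0 rose by 0.93 ± 0.16 (adjusted p = 0.00319) and RPS2 by 0.88 ± 0.18 (adjusted p = 0.00519). The level was 0.52, 0.30 and 0.37 in set 1 libraries 1 to 3 and -0.11, 0.15 and -0.05 in shNC. The libraries also differed in a trend on transcript length (log2 at 7290 minus 1370 bases), at -0.413, -0.108 and -0.222 in set 1 and 0.233, 0.161 and 0.226 in shNC. Removing it took the ribosomal shift relative to other genes from 0.38 to 0.14, still called (adjusted p = 0.00115). Ribosomal members higher were 26 without set 1 library 3 and 21 without shNC library 1 or 3. Type I interferon-stimulated genes fell in 13 and rose in 6 of 36 cases, with 17 not passing (mean -0.25, adjusted p = 0.0359, and adjusted p = 0.558 with an estimated correlation). Interferon genes numbered 14 lower and 8 higher adjusted over the list alone. The antiviral genes IFIT1, RSAD2 and IFIT2 fell by 1.46 ± 0.19 (adjusted p = 0.00128), 1.51 ± 0.28 (adjusted p = 0.00391) and 1.28 ± 0.18 (adjusted p = 0.00155). The interferon level was -0.37, -0.18 and -0.25 in set 1. Interferon genes were not called as a list without shNC library 2 (adjusted p = 0.058), without set 1 library 1 (0.132), with DESeq2 (0.0558), on voom with a quality weight per group (0.144), with a floor of 1 FPKM (0.0546) or with limma on FPKM (0.236). With the GC trend removed 2 interferon members were higher and 11 lower. Stem cell factors fell in 6 of 15 cases, with 0 higher and 9 not passing (mean -0.28, adjusted p = 0.00549, and adjusted p = 0.496 with an estimated correlation). Stem cell factors numbered 7 lower and 1 higher adjusted over the list alone. The transcription factor SOX9 fell by 1.22 ± 0.11 (adjusted p = 0.000259) and the integrin ITGA6 by 0.81 ± 0.10 (adjusted p = 0.0011). The Notch target HES1 stood at -0.58 ± 0.14 (adjusted p = 0.013, up to 0.0637 without shNC library 3 or set 1 library 3). The stem cell level was -0.42, -0.13 and -0.35 in set 1. The list was not called without set 1 library 1 (adjusted p = 0.0561) or without a count filter (0.0849). Its lower members were 3 without set 1 library 3 or shNC library 3, and 4 without set 2 library 2 or shNC library 1.

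Other lists were not called as wholes in set 1, though single members changed. Matrix metalloproteinase and plasminogen genes stood at 0.29 (6 of 21 higher, 2 lower, adjusted p = 0.115, and 0.0383 without set 1 library 1 with 11 higher and 3 lower). The collagenase MMP1 rose by 1.12 ± 0.21 (adjusted p = 0.00389), and TIMP3, a metalloproteinase inhibitor, fell by 1.40 ± 0.09 (adjusted p = 2.41e-05), from 213 to 72.6 FPKM. Without set 1 library 3 or shNC library 1 or 3, or with the GC trend removed, this list had 3 higher and 2 lower members, and 6 and 4 without set 1 library 2. The keratins KRT19 and KRT7 rose by 0.97 ± 0.19 (adjusted p = 0.00444) and 0.80 ± 0.14 (adjusted p = 0.00351). Their epithelial list had 3 higher and 2 lower of 24 (mean 0.05, adjusted p = 0.47), and the mesenchymal list had 3 higher and 4 lower of 21 (mean -0.04, adjusted p = 0.47). Higher epithelial members were 5 without set 1 library 1 or 2, 2 (with 1 lower) without set 1 library 3 or any shNC library, and 3 (with 1 lower) without any set 2 library. Higher mesenchymal members were 5 without set 1 library 1 and 1 without shNC library 3. NF-kB target genes had 6 higher and 5 lower of 31 (mean 0.00, median -0.01, adjusted p = 0.806). They numbered 0 higher and 5 lower without shNC library 1, 0 and 4 without shNC library 3, 1 and 4 without set 1 library 3, and 6 and 11 without set 1 library 2. The NF-kB level was -0.41, 0.24 and -0.02 in set 1 against -0.20, 0.23 and -0.03 in shNC. Among p53 target genes (7 higher, 2 lower of 27, mean 0.16, adjusted p = 0.47) PHLDA3, an AKT repressor, rose by 0.59 ± 0.12 (adjusted p = 0.00548), and stood at 0.34 with the GC trend removed (adjusted p = 0.0567). This list had 2 higher and 1 lower without shNC library 1, and 3 and 0 without shNC library 3 or set 1 library 3. It had 5 and 0 without shNC library 2, 9 higher and 6 lower without set 1 library 1, and 8 and 4 without set 1 library 2. Lower p53 members numbered 1 without set 2 library 2 or 3, and 2 were higher and 1 lower with the GC trend removed. ERK pathway genes had 3 higher and 6 lower of 29 (mean -0.08, adjusted p = 0.433), and 5 and 11 without set 1 library 2. The growth factor HBEGF stood at -0.87 ± 0.20 (adjusted p = 0.00977) and the feedback inhibitor SPRY4 at -0.64 ± 0.11 (adjusted p = 0.00331).

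Endoplasmic reticulum chaperones did not move together in set 1 (3 higher, 4 lower of 28, mean 0.01, median -0.07, test pointing down, adjusted p = 0.793). HERPUD1, a protein of endoplasmic reticulum-associated degradation, rose by 0.90 ± 0.21 (adjusted p = 0.0114). The chaperone list had 1 lower member without set 1 library 3 or shNC library 1 or 3, 7 higher and 4 lower without set 1 library 1, 1 higher and 3 lower without shNC library 2, and 3 and 2 without set 2 library 2 or 3. Genes tied to lung metastasis, a set chosen by others on sublines of this cell line, had 6 higher and 5 lower of 15 (mean 0.31, adjusted p = 0.654). Their level was 0.20, 0.19 and 0.31 in set 1 libraries 1 to 3. Of 3 Schlafen genes SLFN12, a partner of PDE3A in cells treated with certain PDE3A ligands, fell by 0.98 ± 0.19 (adjusted p = 0.00517, and 0.0564 with the GC trend removed). SLFN5 stood at 1.73 ± 0.50 (adjusted p = 0.0254, up to 0.0841 without any shNC library or set 1 library 3), and at 1.12 without set 1 library 2. Luminal markers (mean 0.13, adjusted p = 0.433), leukocyte markers (0.24, adjusted p = 0.47) and replication-dependent histones (0.06, 0 of 13 called, adjusted p = 0.857) were not called. The histone genes HIST1H2BK and HIST1H1C, of a class whose mRNAs mostly lack poly(A) tails, stood at -0.15 ± 0.10 (adjusted p = 0.253) and -0.22 ± 0.10 (adjusted p = 0.116).

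Across all genes, set 1 differed from shNC in 1756 higher and 1959 lower of 12599 genes (3715, adjusted p < 0.05), of which 204 higher and 95 lower changed at least 2-fold. KLHDC7B, a kelch protein gene, rose by 3.60 ± 0.74 (adjusted p = 0.00601) from 0.103 ± 0.04 to 1.15 ± 1.01 FPKM. In set 1 libraries 1 to 3 it stood at 0.19, 2.21 and 1.05 FPKM against 0.08 to 0.15 in shNC, and its change was 2.73 without set 1 library 2. The read-through gene DNAJC25-GNG10, whose count is uncertain, stood at -1.75 ± 0.46 (adjusted p = 0.0168, up to 0.0791 without shNC library 1 or set 1 library 3, and 0.0601 with the GC trend removed). Calls numbered 1872, 2341 and 1908 without shNC library 1, 2 or 3, and 4847, 5161 and 1901 without set 1 library 1, 2 or 3. With set 1 and shNC fitted alone 2754 were called. With the GC trend of each library removed 1806 were called, 1358 of them among the 3715. Between genes of 38.9 and 62.4% GC that trend differed by 0.64, 0.11 and 0.37 log2 in set 1 libraries 1 to 3, -0.17, -0.30 and -0.16 in shNC, and -0.40, -0.10 and 0.02 in set 2. On FPKM values with limma the median of all genes was at -0.15, and 953 genes were higher and 2887 lower.

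**Figure D2:**
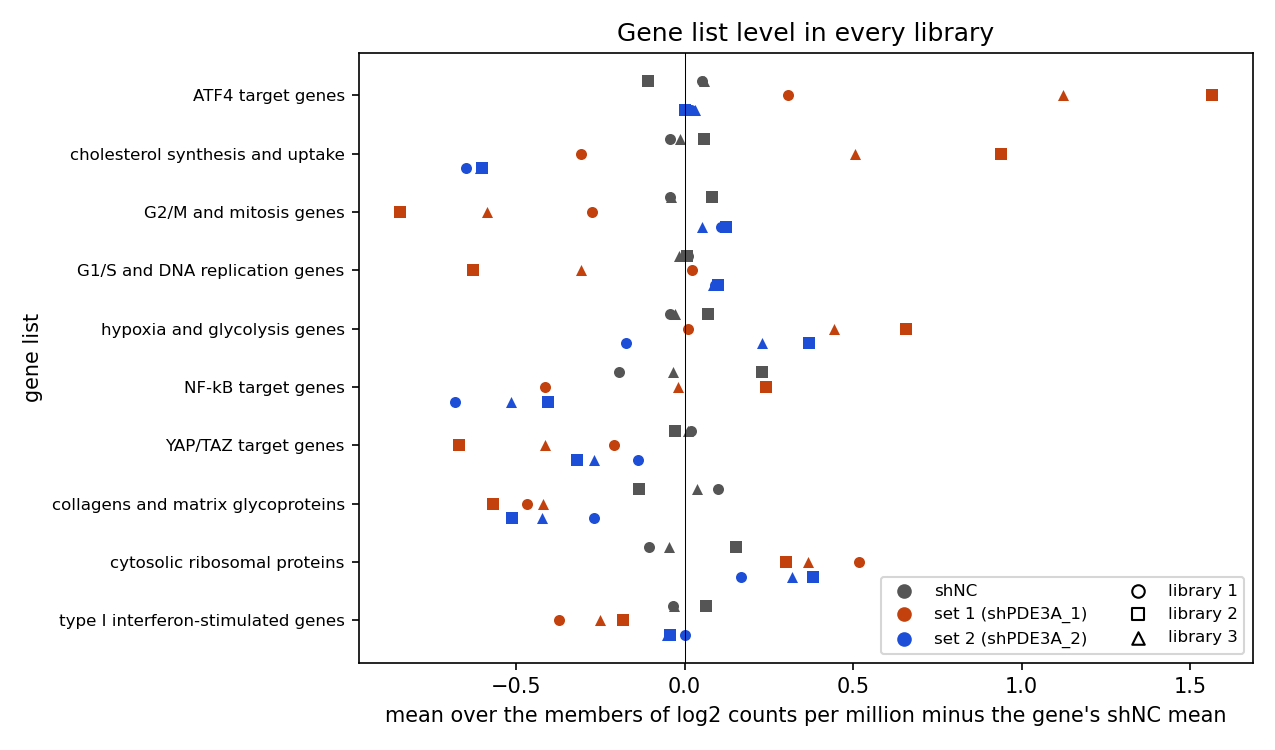
Level of 10 gene lists in each of the 9 libraries. The horizontal axis is the mean over list members of log2 CPM minus each gene's mean in shNC. Points are libraries, coloured by group, with the marker giving the library number, and libraries of set 1 are spread for ATF4, cholesterol, cell cycle and hypoxia genes.

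In set 2 against shNC, genes of the NF-kB pathway, matrix, cholesterol and YAP/TAZ stood lower as groups, with few single genes called in the fit of all 9 libraries. NF-kB target genes had 4 lower and 0 higher of 31, with 27 not passing (mean -0.55, adjusted p = 1.66e-12, and adjusted p = 0.222 with an estimated correlation). NF-kB members were 16 lower and 3 higher adjusted over the list alone, and 17 and 3 when set 2 and shNC were fitted alone. The chemokine CXCL1 fell by 2.11 ± 0.28 (adjusted p = 0.00868) from 78.7 to 17.7 FPKM and the lymphotoxin gene LTB by 1.94 ± 0.28 (adjusted p = 0.0173). TNF stood at -2.23 ± 0.51 (adjusted p = 0.0888). The NF-kB level was -0.68, -0.40 and -0.51 in set 2 libraries 1 to 3. Without shNC library 1, 2 or 3 the lower members numbered 1, 0 and 2. They were 16, 15 and 2 without set 1 library 1, 2 or 3, and without set 2 library 1, 2 or 3 they numbered 0, 1 and 0. CXCL1 lost its call without shNC library 2 or any set 2 library (adjusted p up to 0.0991), and LTB without shNC library 1 or 2 or set 2 library 1 or 3 (up to 0.116). With set 2 and shNC fitted alone both were called (adjusted p = 7.25e-07 and 0.000116).

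Of 31 collagens and matrix glycoproteins 6 fell, 0 rose and 25 did not pass in set 2 (mean -0.41, adjusted p = 5.1e-16, and adjusted p = 0.0766 with an estimated correlation). Matrix genes were 15 lower and 1 higher adjusted over the list alone, and 17 and 1 when set 2 and shNC were fitted alone. THBS2 fell by 1.80 ± 0.21 (adjusted p = 0.00363) and EFEMP1 by 1.03 ± 0.11 (adjusted p = 0.00155), both in every fit with a library left out. The matrix level was -0.27, -0.51 and -0.42. LAMA5 stood at -0.58 ± 0.11 (adjusted p = 0.0402). Lower matrix members numbered 14 and 11 without set 1 library 1 or 2, and 2 without any other library. Cholesterol synthesis and uptake genes had 1 lower and 0 higher of 30, and 29 did not pass in set 2. Their mean was -0.62 (adjusted p = 1.45e-09, and adjusted p = 0.365 with an estimated correlation), with 4 lower adjusted over the list alone. The cholesterol level was even across set 2, at -0.65, -0.60 and -0.61. Lower members were 18 and 7 without set 1 library 1 or 2 and 0 without any other library. With set 2 and shNC fitted alone 19 cholesterol genes were lower and 0 higher. LAMA5 lost its call without any shNC library, any set 2 library or set 1 library 3 (adjusted p up to 0.28). With set 2 and shNC fitted alone LAMA5 was called (adjusted p = 0.000581).

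YAP/TAZ target genes had 2 lower and 0 higher of 28, with 26 not passing in set 2 (mean -0.24, adjusted p = 1.56e-07, and adjusted p = 0.25 with an estimated correlation). YAP/TAZ members lower adjusted over the list alone were 6. NUAK2 stood at -0.94 ± 0.15 (adjusted p = 0.0235). ERK pathway genes had 3 lower and 0 higher of 29, with 26 not passing (mean -0.22, adjusted p = 8.12e-06, and adjusted p = 0.0766 with an estimated correlation), and 3 were lower adjusted over the list alone. SPRY4 stood at -0.64 ± 0.11 (adjusted p = 0.0334). Stem cell factors had 2 lower and 0 higher of 15, with 13 not passing (mean -0.26, adjusted p = 8.8e-05, and adjusted p = 0.222 with an estimated correlation), and 4 were lower adjusted over the list alone. SOX9 stood at -0.67 ± 0.11 (adjusted p = 0.0213) and HES1 at -0.79 ± 0.14 (adjusted p = 0.0389). Mesenchymal genes had 3 lower and 1 higher of 21, with 17 not passing (mean -0.21, adjusted p = 0.000734, and adjusted p = 0.0766 with an estimated correlation). Mesenchymal members were 6 lower and 1 higher adjusted over the list alone. CDH11, osteoblast cadherin, fell by 2.08 ± 0.22 (adjusted p = 0.00167). The actin-binding TAGLN stood at 1.54 ± 0.24 (adjusted p = 0.0213). Lower members numbered 7 and 5 (YAP/TAZ), 6 and 6 (ERK), and 5 and 4 (stem cell) without set 1 library 1 or 2, and 0 in each list without any other library. Mesenchymal genes had 1 lower and 0 higher member without any library but those. The fit of set 2 and shNC alone called 12 YAP/TAZ genes lower, 9 ERK genes lower and 1 higher, and 5 stem cell factors lower. It called 5 mesenchymal genes lower and 1 higher. The calls of NUAK2, SPRY4, SOX9, HES1 and TAGLN were lost in the same 7 fits, without any shNC or set 2 library or set 1 library 3. Their adjusted p values there reached 0.192, 0.239, 0.188, 0.258 and 0.148. With set 2 and shNC fitted alone all of them were called (adjusted p from 6.37e-08 for TAGLN to 0.00115 for HES1). The calls by the set test of all these lists held without any 1 library.

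Ribosomal protein genes stood at a mean of 0.29 in set 2 (adjusted p = 4.36e-20, and adjusted p = 0.292 with an estimated correlation), with 0 of 78 members called. They were 13 higher adjusted over the list alone and 9 higher with DESeq2. Ribosomal members higher were 32 when set 2 and shNC were fitted alone, and 16 and 10 without set 1 library 1 or 2. Their level was 0.17, 0.38 and 0.32 in set 2 libraries 1 to 3, where the length trend was 0.185, -0.027 and -0.035, so the library with a trend like that of shNC had the lowest level. Removing the length trend took the shift relative to other genes from 0.30 to 0.18 (adjusted p = 7.01e-09). Mitosis genes were not lower in set 2, with 0 of 39 called and a mean of 0.10 (adjusted p = 0.0636, and 0.0283 when set 2 and shNC were fitted alone). G1/S genes stood at 0.09 (0 of 36 called, adjusted p = 0.102), and the fit of set 2 and shNC alone called 2 mitosis and 4 G1/S genes higher. ATF4 target genes had a mean of 0.02 and a median of -0.01 (1 of 33 higher, adjusted p = 0.698). That member was SLC7A5, an amino acid transporter named after its values were seen, at 0.64 ± 0.12 (adjusted p = 0.0491). SLC7A5 was not called without any library but set 1 library 1 or 2. Hypoxia genes (0.18, adjusted p = 0.0701) and lung metastasis genes (-0.03, 3 of 15 lower, adjusted p = 0.0636) were not called. Neither were epithelial genes (-0.14, adjusted p = 0.147), p53 targets (-0.04, adjusted p = 0.698) and endoplasmic reticulum chaperones (0.07, adjusted p = 0.266). Interferon-stimulated genes (mean -0.03, median 0.05, adjusted p = 0.829) and metalloproteinase genes (mean -0.03, median -0.21, adjusted p = 0.373) were not called. The same holds for luminal markers (mean -0.01, median -0.06, test pointing up, adjusted p = 0.957), leukocyte markers (mean -0.01, median 0.11, adjusted p = 0.698) and histones (0.07, adjusted p = 0.698). Of these, mitosis genes were called without set 1 library 1 or 2 (adjusted p = 0.046 and 0.0442), shNC library 2 or set 2 library 3, and G1/S genes without set 1 library 2 (0.0442). Lower lung metastasis members numbered 1 without shNC library 2 or any set 2 library, and 3 were also higher without set 1 library 1 or 2. Lung metastasis genes were called without shNC library 1 or 2, hypoxia genes without set 2 library 1 and chaperones without set 2 library 2 (0.0296). The luminal marker PRLR, the prolactin receptor, stood at 0.78 ± 0.14 (adjusted p = 0.0334, up to 0.207 without any shNC library, any set 2 library or set 1 library 3). With set 2 and shNC fitted alone PRLR was called (adjusted p = 0.00115).

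Across all genes, set 2 differed from shNC in 21 higher and 55 lower genes (76, adjusted p < 0.05; 12 higher and 16 lower at least 2-fold), with 1576 genes at an unadjusted edgeR p under 0.05. LIPG, endothelial lipase, stood at -3.50 ± 0.57 (adjusted p = 0.0223) with 1.32 ± 0.07 FPKM in shNC and 0.117 ± 0.05 in set 2. LIPG lost its call without any shNC library, any set 2 library or set 1 library 3 (adjusted p up to 0.162). With set 2 and shNC fitted alone it was called (adjusted p = 3.26e-07). Fitted with shNC alone, set 2 differed in 617 higher and 815 lower genes (1432, all 76 among them). It differed with DESeq2 in 113 higher and 239 lower, and on voom with a quality weight per group in 403 higher and 591 lower. Calls numbered 15, 13 and 15 without shNC library 1, 2 or 3. They numbered 745, 432 and 20 without set 1 library 1, 2 or 3, and 19, 13 and 14 without set 2 library 1, 2 or 3.

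**Figure D3:**
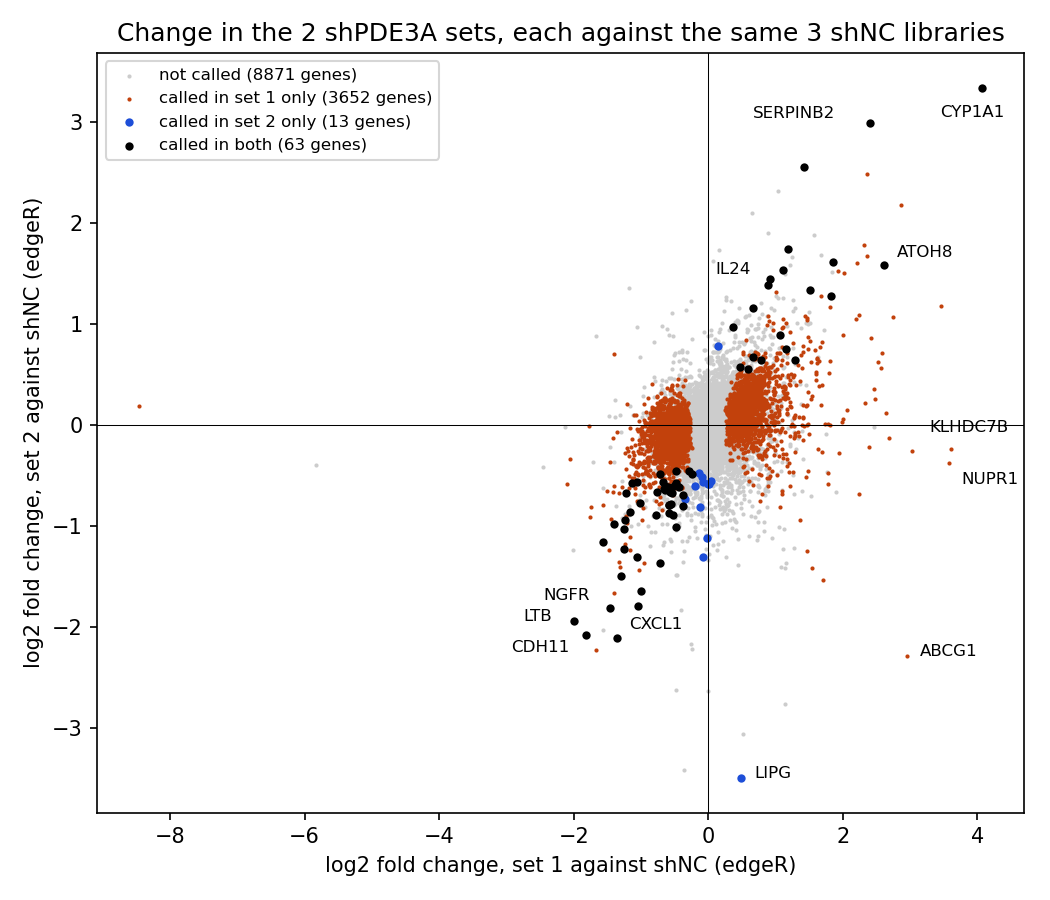
Change of each of the 12599 tested genes in set 1 (horizontal axis) and set 2 (vertical axis), as log2 fold change against the same 3 shNC libraries. Colours mark genes called in neither set, in set 1 only, in set 2 only and in both. Because both axes share the shNC libraries, part of the slope is present without any shared effect.

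The genes called in both sets included CYP1A1, a cytochrome P450 enzyme of xenobiotic metabolism, SERPINB2, an inhibitor of plasminogen activation, and the transcription factor ATOH8 on the higher side, and CDH11, NGFR and PTX3 on the lower side. CYP1A1 rose by 4.06 ± 0.12 in set 1 and 3.34 ± 0.12 in set 2 (adjusted p = 2.44e-08 and 1.73e-07), from 1.36 ± 0.04 to 20.6 ± 0.69 and 13.5 ± 1.99 FPKM. SERPINB2 rose by 2.40 ± 0.15 and 2.99 ± 0.15 (adjusted p = 2.41e-05 and 4.04e-06). ATOH8 rose by 2.61 ± 0.16 and 1.58 ± 0.17 (adjusted p = 2.41e-05 and 0.00167), and the cytokine IL24 by 0.91 ± 0.15 and 1.45 ± 0.15 (adjusted p = 0.00256 and 0.00155). The nerve growth factor receptor NGFR fell from 68.6 ± 2.31 FPKM to 22.3 ± 1.63 and 18.9 ± 0.58, at -1.47 ± 0.10 and -1.82 ± 0.10 (adjusted p = 4.66e-05 and 9.25e-06). CDH11 stood at -1.82 ± 0.22 and -2.08 ± 0.22 (adjusted p = 0.00106 and 0.00167). The pentraxin PTX3 stood at -1.56 ± 0.12 and -1.16 ± 0.12 (adjusted p = 8.02e-05 and 0.00152). PI16, a peptidase inhibitor, stood at -1.07 ± 0.12 and -1.31 ± 0.12 (adjusted p = 0.000861 and 0.00085) and TIMP3 at -1.40 ± 0.09 and -0.98 ± 0.09 (adjusted p = 2.41e-05 and 0.00085). These genes and EFEMP1 and THBS2, 11 in all, were called in both sets whichever library was left out.

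NEURL1, an E3 ubiquitin ligase of Notch signalling, stood at 1.86 ± 0.28 in set 1 and 1.61 ± 0.28 in set 2 (adjusted p = 0.00187 and 0.0334). CYSRT1 stood at 1.52 ± 0.18 and 1.34 ± 0.18 (adjusted p = 0.00106 and 0.00868). ASB2, part of a ubiquitin ligase, stood at 1.82 ± 0.20 and 1.28 ± 0.20 (adjusted p = 0.000682 and 0.0204), and TAGLN at 1.11 ± 0.24 and 1.54 ± 0.24 (adjusted p = 0.00799 and 0.0213). LTB stood at -2.00 ± 0.28 and -1.94 ± 0.28 (adjusted p = 0.00161 and 0.0173) and CXCL1 at -1.36 ± 0.27 and -2.11 ± 0.28 (adjusted p = 0.00546 and 0.00868). The cytokine CSF2 stood at -1.30 ± 0.24 and -1.49 ± 0.25 (adjusted p = 0.00428 and 0.0246), and the potassium channel subunit KCNS3 at -1.26 ± 0.24 and -1.23 ± 0.24 (adjusted p = 0.00438 and 0.0495). Their set 1 calls held without any 1 library. Set 2 calls of NEURL1, TAGLN, CSF2 and KCNS3 were lost without any shNC library, any set 2 library or set 1 library 3 (adjusted p up to 0.179, 0.148, 0.158 and 0.294). That of ASB2 was lost without any shNC library, set 1 library 3 or set 2 library 2 or 3 (up to 0.127), and that of CYSRT1 without any shNC library or set 2 library 2 (up to 0.0709). CXCL1 was not called in set 2 without shNC library 2 or any set 2 library (up to 0.0991), nor LTB without shNC library 1 or 2 or set 2 library 1 or 3 (up to 0.116). With set 2 and shNC fitted alone all genes of this paragraph were called in set 2 (adjusted p from 6.37e-08 for TAGLN to 0.00152 for KCNS3).

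In all, 20 genes were higher and 43 lower in both sets (63, 0 opposite, 82.9% of the set 2 calls), 9 and 11 of them at least 2-fold in both. Chance overlap of the calls (n1 × n2 / N) gives 2.93 and 8.55, and the log2 fold changes correlated at 0.366 with a covariance of 0.0542. In 20 simulated draws with 3 shared controls and no change in either set the correlation was 0.291 (0.27 to 0.31) and the covariance 0.0116. Shared calls were 0 there, but with no changed genes this says little about shared calls of sets that each change. Part of the excess may come from the shared controls, and the covariance difference of 0.0426 estimates what is beyond them. The simulated counts held no trend on transcript length or GC content, so this difference may include such trends. The length trend was 0.161 to 0.233 in shNC, -0.413 to -0.108 in set 1 and 0.185, -0.027 and -0.035 in set 2 libraries 1 to 3. Shared calls numbered 15, 12 and 15 without shNC library 1, 2 or 3, 363, 294 and 18 without set 1 library 1, 2 or 3, and 18, 13 and 13 without set 2 library 1, 2 or 3. With each set fitted on its own with shNC, 235 genes were higher and 216 lower in both and 23 were opposite, against 67.4 and 91.2 by chance. These 451 shared genes stood beside 1432 set 2 calls in its own fit. In the fit of all 9 libraries both sets share the controls and 1 spread per gene, which favours joint calls. The 82.9% and the 0 opposite are therefore partly set by that fit. DESeq2 called 91 higher and 128 lower in both.

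Set 1 and set 2, tested against each other, differed most in ATF4 target genes, cholesterol genes and mitosis genes. ATF4 targets were higher in set 1 than in set 2 in 22 of 33 cases, with 0 lower and 11 not passing (mean 1.11, adjusted p = 1.84e-15, and adjusted p = 0.41 with an estimated correlation). CHAC1 was higher by 2.53 ± 0.35 (adjusted p = 0.00287) and NUPR1 by 3.95 ± 0.74 (adjusted p = 0.00633). Higher ATF4 targets were 13 without set 1 library 3 and 12 without set 2 library 1. Cholesterol genes were higher in 21 of 30, with 0 lower and 9 not passing (mean 1.13, adjusted p = 1.34e-15, and adjusted p = 0.41 with an estimated correlation), or 10 without set 2 library 1. TM7SF2 was higher by 1.02 ± 0.15 (adjusted p = 0.0032). Mitosis genes were lower in 26 of 39, with 0 higher and 13 not passing (mean -0.64, adjusted p = 3e-25, and adjusted p = 0.41 with an estimated correlation). ASPM stood at -0.93 ± 0.10 (adjusted p = 0.00179) and CENPF at -0.87 ± 0.10 (adjusted p = 0.00186), and 16 mitosis genes were lower with the GC trend removed. G1/S genes were lower in 17 of 36, with 0 higher and 19 not passing (mean -0.36, adjusted p = 6.43e-07, and adjusted p = 0.41 with an estimated correlation). Lower G1/S genes were 4 without set 1 library 3, 5 and 6 without set 2 library 1 or 2, and 4 with the GC trend removed.

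NF-kB target genes were higher in set 1 than in set 2 in 9 of 31 cases, with 0 lower and 22 not passing (mean 0.55, adjusted p = 7.22e-05, and adjusted p = 0.41 with an estimated correlation). The higher members numbered 18 without set 1 library 1, 3 without set 1 library 3, and 2, 5 and 5 without set 2 library 1, 2 or 3. Metalloproteinase and plasminogen genes were higher in 9 and lower in 2 of 21, with 10 not passing (mean 0.32, adjusted p = 0.0192, and adjusted p = 0.41 with an estimated correlation). SERPINB2 stood at -0.59 ± 0.13 (adjusted p = 0.0122, up to 0.0652 without set 1 library 3 or set 2 library 1, and 0.0918 with the GC trend removed). This list was not called without set 1 library 2 (adjusted p = 0.116) or with the GC trend removed (0.072). Its higher and lower members were 2 and 0 without set 1 library 3, and 5 and 2 without shNC library 1 or 3. They were 2 and 1, 2 and 2, and 4 and 2 without set 2 library 1, 2 or 3. Interferon-stimulated genes were lower in 11 and higher in 4 of 36, with 21 not passing (mean -0.22, adjusted p = 0.0373, and adjusted p = 0.41 with an estimated correlation). IFIT1 stood at -1.10 ± 0.19 (adjusted p = 0.0052, and 0.0595 with the GC trend removed). As a list they were not called without set 1 library 1 (adjusted p = 0.149, with 7 higher and 13 lower), on voom with a quality weight per group (0.062) or with limma on FPKM. Interferon genes numbered 2 higher and 8 lower without set 1 library 3 or set 2 library 1, and 2 and 9 without set 2 library 2. Ribosomal protein genes were at 0.11 (2 of 78 higher, adjusted p = 0.0465, and adjusted p = 0.713 with an estimated correlation), a call lost without set 1 library 1 (adjusted p = 0.712) or set 2 library 1 (0.318). Ribosomal members called between the sets were 14 higher and 1 lower without set 1 library 2, 1 higher without any shNC library and 0 without set 1 library 3 or any set 2 library. With the length trend removed their shift relative to other genes turned to -0.0327 and was not called (adjusted p = 0.931), nor was it called with the replicate block or limma on FPKM. Matrix genes (mean -0.06, 5 higher and 3 lower of 31, adjusted p = 0.704) and YAP/TAZ targets (mean -0.16, 2 higher and 7 lower of 28, adjusted p = 0.0748) were not called between the sets. Matrix genes had 6 higher and 10 lower without set 1 library 1, and 2 and 2 without set 1 library 3 or set 2 library 1 or 2. YAP/TAZ targets had 1 higher and 2 lower without set 1 library 3 or set 2 library 1. They were called without set 1 library 1 (3 higher, 12 lower) or set 2 library 2 (adjusted p = 0.0277).

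Among called genes the widest gap between the sets was that of ABCG1, a cholesterol exporter, at 5.24 ± 0.96 (adjusted p = 0.00613), with 2.12 ± 2.04 FPKM in set 1 and 0.06 ± 0.02 in set 2. The ABCG1 gap was 4.25 without set 1 library 2, and set 1 library 1 (0.19 FPKM) lay below the shNC libraries (0.24 to 0.39). LIPG stood at 3.99 ± 0.56 (adjusted p = 0.00287). On the lower side stood RBM14-RBM4, a read-through gene with an uncertain count, at -1.65 ± 0.44 (adjusted p = 0.0229), BGLAP, osteocalcin, at -1.56 ± 0.48 (adjusted p = 0.0388) and C11orf86 at -1.55 ± 0.50 (adjusted p = 0.0466). RBM14-RBM4 lost its call without set 1 library 3 or set 2 library 2 or 3 (adjusted p up to 0.0927), and BGLAP and C11orf86 without any library but set 1 library 1 (up to 0.118 and 0.141). KRT19 was higher in set 1 by 0.94 ± 0.19 (adjusted p = 0.00767, and 0.0637 with the GC trend removed), and EGR1 by 2.25 ± 0.31 (adjusted p = 0.00284). In all, 1318 genes were higher and 1474 lower in set 1 than in set 2 (2792, adjusted p < 0.05), 236 and 41 of them at least 2-fold. Limma on FPKM gave 694 and 1905 with the median of all genes at -0.10. Calls numbered 4310 and 957 without set 1 library 1 or 3, and 1048, 1462 and 1835 without set 2 library 1, 2 or 3. They numbered 1154 with the 2 sets fitted alone, 1297 on voom with a quality weight per group and 716 with the GC trend removed.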

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

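The tests weighed below on GC content, transcript length and library mixture were chosen only after these results were seen. Each gene or list in the next 2 paragraphs differed between set 1 and set 2 in the direct test of 1 set against the other (adjusted p < 0.05), and its value is log2 set 1 minus set 2.

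Higher in set 1 were ABCG1 5.24, LIPG 3.99, NUPR1 3.95, KLHDC7B 3.84, CHAC1 2.53, EGR1 2.25, SESN2 2.11, BBC3 1.97, SLFN5 1.73, ATF3 1.29, ATOH8 1.03 and TM7SF2 1.02. Smaller gaps were KRT19 0.94, CLDN7 0.88, THBS2 0.75, KRT7 0.74, CYP1A1 0.72, PMVK 0.44, PHLDA3 0.43 and NGFR 0.35. Higher lists were cholesterol synthesis and uptake 1.13, ATF4 targets 1.11, NF-kB targets 0.55, metalloproteinases and plasminogen activation 0.32 and ribosomal proteins 0.11. The ribosomal call was lost with the length trend removed, where the shift relative to other genes turned to -0.0327 (adjusted p = 0.931). With the GC trend removed the gaps of KRT19, CLDN7, THBS2, KRT7, PMVK, PHLDA3, NGFR and BBC3 were not called. THBS2 (0.73) and BBC3 (1.74) kept most of their gap there, while NGFR went to 0.09. With each library left out in turn PMVK was called in 1 of 9 fits, SLFN5 and NGFR in 2, THBS2 in 3, PHLDA3 in 5, CLDN7 in 7 and BBC3 in 8. Of these only CLDN7 and BBC3 were called on voom with group quality weights, and only BBC3 with limma on FPKM. With the 2 sets fitted alone SLFN5, CLDN7, THBS2, PMVK and NGFR were not called (adjusted p up to 0.0967).

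Lower in set 1 were RBM14-RBM4 -1.65, BGLAP -1.56, C11orf86 -1.55, IFIT1 -1.1, PDE4B -1.02, ASPM -0.93, CENPF -0.87, SLFN12 -0.86, MCM10 -0.85, SDPR -0.85, PDE7A -0.83, CLSPN -0.8 and MKI67 -0.76. Smaller gaps were IFIT2 -0.67, PRLR -0.64, SERPINB2 -0.59, PDIA4 -0.58, TYMS -0.57, LAMA5 -0.56, SOX9 -0.55, IL24 -0.54, ITGA6 -0.45, TIMP3 -0.42 and PTX3 -0.41. Lower lists were G2/M and mitosis -0.64, G1/S and DNA replication -0.36 and interferon-stimulated genes -0.22. With the GC trend removed the gaps of IFIT1, PDE4B, SLFN12, MCM10, SDPR, CLSPN, IFIT2, PRLR, SERPINB2, TYMS, IL24, ITGA6 and PTX3 and the list of metalloproteinase genes above were not called. TYMS (-0.52) kept most of its gap there, while ITGA6 went to -0.23. In fits with a library left out BGLAP and C11orf86 were called in 1 of 9 and PTX3 in 3. RBM14-RBM4, IFIT2, IL24, PDIA4, TYMS, MCM10 and CLSPN were called in 6, PDE4B, SDPR and SERPINB2 in 7, and SLFN12 and TIMP3 in 8. On voom with group quality weights RBM14-RBM4, BGLAP, C11orf86, PDE4B, PDE7A, SLFN12, IFIT2, PRLR, PDIA4, IL24 and PTX3 were not called, nor RBM14-RBM4 with limma on FPKM. With the 2 sets fitted alone RBM14-RBM4, BGLAP, C11orf86, PDE4B, SLFN12, MCM10 and SDPR were not called. Nor were CLSPN, IFIT2, PDIA4, TYMS, ITGA6, TIMP3 and PTX3 (adjusted p up to 0.122).

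Set 1 had 48.9 times as many calls as set 2, and a share of this likely comes from the spread shared by the fit. With the GC trend removed set 1 had 1806 calls, 48.6% of the number without that step and narrowly under the bound set for it. Of its 3715 main calls 1358 were among these. With the length trend removed it had 2775 calls (74.7%), 2272 of them main calls. The ratio of calls after the GC step was still 16.6. Both steps also take out any real change that follows GC content or length, so these falls alone do not show a technical cause. Leaving out set 1 library 1, 2 or 3 gave ratios of 6.51, 11.9 and 95. Library 3 resembled a mixture of libraries 1 and 2, so part of either profile stays when that library is left out. The ratios can therefore not exclude 1 divergent library. The spread of the set 1 libraries, shared by the fit, hid calls of set 2: its own fit called 18.8 times as many genes, and with own fits the ratio was 1.92. A stronger response of set 1 cells remains possible for that remainder, and the tests here cannot separate it from a culture or library difference.

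Mitosis genes were lower in set 1 but not in set 2. Relative to other genes the G2/M list kept 77% of its shift with the GC trend removed (-0.43) and 103% with the length trend removed (-0.58), so neither trend is likely to make it. Slower division in set 1, or a denser or stressed culture, could each give this, and the list level was lowest in set 1 library 2, where ATF4 targets were highest.

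Set 1 library 3 lay between libraries 1 and 2 for 1587 of 1688 genes (94%) at least 2-fold apart in those 2. A mixture with 49% of library 1 left a chi-square per degree of freedom of 2.26, against 2.76 to 13.1 for pairs of shNC libraries. Fitted the same way, shNC library 3 as a mixture of the other 2 left 2.61, with 75.6% of genes between, and the other 7 libraries left 3.51 to 33.8. As a single pair, shNC library 3 was already at 2.76 from shNC library 1. Set 1 library 3 was at 36.6 and 30.9 from libraries 1 and 2, which were 123 apart, so only the mixture came close to it. The fit alone does not tell pooled material from a separate culture of intermediate levels. Library 3 may hold pooled material of the other 2, or come from a culture with part of the cells in each state. If it was pooled, set 1 has fewer than 3 independent samples and its p values are too small.

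Splits of the 6 libraries into 2 groups of 3 number 10 for each pair of groups, too few for a share under 0.05. In each pair only the real split, 1 of 10, called as many genes as the labels did: 2754 in set 1 (highest other 1), 1432 in set 2 (highest other 1) and 1154 between the sets (highest other 0). Of 100 splits of the 9 libraries into 3 groups, 2 had as many shared calls as the labels, the real one with 63 and another with 1625. That other split used the 3 set 1 libraries as the reference, so it reflects how far set 1 stands from all other samples.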

How the results depend on the processing

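Voom with group weights and the GC and length steps were added only after the results were seen. Groups fitted alone leave the spread of the set 1 libraries out of the fit of set 2. They also leave the closer set 2 libraries out of the fit of set 1, and the closer shNC libraries out of the comparison between the sets. For the other differences below the cause was not tested. Main calls were 3715 in set 1, 76 in set 2, 2792 between the sets and 63 shared. DESeq2 called 352 in set 2 and 219 shared. Groups fitted alone gave 2754 in set 1, 1432 in set 2, 1154 between the sets and 451 shared. Voom with group quality weights gave 994 in set 2, 1297 between the sets and, changed in both shPDE3A sets, 400. With the GC trend removed 1806 were called in set 1 and 716 between the sets. At least 2-fold were 299, 28, 277 and 20. A test of both sets together as 6 libraries, which a change in 1 set alone can pass, called 1235 genes. With the replicate block, 25 were called in set 2 and 24 shared. Deviations of libraries of the same number correlated at -0.109 to 0.122, against -0.141 to 0.115 for different numbers across groups. No strong pairing by number is seen, and a weak one is not excluded. Leaving out 1 library gave 1872 to 5161 calls in set 1, 13 to 745 in set 2, 957 to 4310 between the sets and 12 to 363 shared. Lists called, 10, 8 and 8 in the main test, fell to 0, 0 and 0 with an estimated correlation, fry called 5 in set 2, and a floor of 1 FPKM gave 13 between the sets. With fry (adjusted p), set 1 lost G1/S (0.0968), hypoxia (0.121) and cholesterol genes (0.152). It gained cAMP components (0.0198), ERK genes (0.0315), phosphodiesterases and luminal markers (0.0396 each). Set 2 lost NF-kB, YAP/TAZ and ribosomal genes (0.0799 each) and cholesterol genes (0.217), and gained lung metastasis genes (0.0272). Between the sets fry dropped NF-kB, metalloproteinase, G1/S and ribosomal lists and added epithelial, ERK and lung metastasis lists. Cytosolic ribosomal proteins, shPDE3A_1 against shPDE3A_2, turned from higher to -0.0327, not called, with the length trend removed. Of 85 named genes, set 1 calls were unchanged for 85 with DESeq2, 82 with the block and 67 with the GC trend removed (16 weaker, 2 stronger). With set 1 and shNC fitted alone they were unchanged for 72 and weaker for 13, including MCM10, CLSPN, AKAP12, NDRG1 and SLFN5. Without shNC library 3 they were unchanged for 65 and weaker for 20. Set 2 calls were weaker for 15, 16 and 14 genes without shNC library 1, 2 or 3. They were weaker for 14, 15 and 15 without set 2 library 1, 2 or 3, and for 13 without set 1 library 3. PDE3A, at 0 to 4.0 expected counts, is beyond what this depth resolves.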

Other observations

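The GO terms, the extra lists and the tests of the ideas below were chosen only after the results were seen. Among 364 GO terms of 20 to 500 tested genes, camera called 3 up and 9 down in set 1, 12 and 23 in set 2, and 5 and 24 between the sets, and 0 with an estimated correlation. In set 1, RNA transport genes stood at -0.32 (18 of 43 lower, 2 higher, adjusted p = 0.00018, and 0.816 with an estimated correlation) and glucose transport genes at -0.25 (15 of 32 lower, 3 higher, adjusted p = 0.000447, and 0.816 with an estimated correlation). In set 2, cell-cell adhesion genes stood at -0.30 (6 of 92 lower, adjusted p = 5.19e-07, and 0.392 with an estimated correlation), cholesterol transport at -0.42 (2 of 22 lower, adjusted p = 0.000953, and 0.712 with an estimated correlation) and the electron transport chain at 0.14 (0 of 44 called, adjusted p = 0.000863, and 0.712 with an estimated correlation). Between the sets, genes of cytokine-mediated signalling were higher in set 1 (25 of 82 higher, 5 lower, mean 0.32, adjusted p = 0.000222, and 0.819 with an estimated correlation).

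CYP1A1 is the best known target of the aryl hydrocarbon receptor, so its rise could reflect that receptor in both sets. Of 6 other targets tested, 0 were called higher in both sets (other members called higher in both sets: 0). In set 1 CYP1B1 rose by 2.23 ± 0.34, AHRR by 1.08 ± 0.24 and TIPARP by 0.78 ± 0.24, and with set 2 and shNC fitted alone CYP1B1 was also called in set 2 (adjusted p = 3.05e-06), at 33.4 FPKM in shNC, 143 in set 1 and 68.9 in set 2. In the fit of all 9 libraries only 21 of 12599 genes were called higher in set 2, so the count of 0 cannot exclude the receptor there. The receptor idea may hold for set 1 and stays open for set 2. A receptor antagonist with CYP1A1 and CYP1B1 as readouts would test it.

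FTL, ferritin light chain, stood at 1.15 ± 0.11 in set 1 and 0.75 ± 0.11 in set 2 (adjusted p = 0.00047 and 0.0184), called in both in only 3 of the 9 fits with a library left out. NRF2, which drives it, could be active in both. Of 22 other NRF2 target genes 8 rose and 1 fell in set 1, and 0 were called higher in both sets (other members called higher in both sets: 0), with 1, OSGIN1, when set 2 and shNC were fitted alone. Since the fit of all 9 libraries called only 21 genes higher in set 2, its count of 0 says little. With 1 member called higher in the fit of set 2 and shNC alone, a general rise of NRF2 targets in both sets is unlikely here. Iron load and FTL protein would tell more.

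HLA-DRB1, HLA-DRB3, HLA-DRB5 and HLA-DPB1 were first seen to be higher in set 1 than in set 2. Of the 8 members of MHC class II and its loading machinery not first seen, 6 were too (members not first seen that are called higher in set 1 than in set 2: 6). CD74 was higher by 0.85 ± 0.16. Of all 12599 genes tested, 1318 were higher in set 1 than in set 2. Against shNC 5 of the 8 were called higher in set 1 and 0 were called in set 2. HLA-DRB1 stood at 0.92 ± 0.14 in set 1 (adjusted p = 0.00211). In set 2 it stood at -0.50 ± 0.14 (adjusted p = 0.172, and 0.000912 with set 2 and shNC fitted alone). That own fit also called HLA-DRB3 (adjusted p = 0.000527), HLA-DRB5 (0.00243) and HLA-DPB1 (0.00693), each below 0 in set 2. Part of the gap of these genes may therefore lie in set 2. Reads of these close paralogs may be shared by the quantification, so flow cytometry of HLA-DR would be the test.

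Set 1 libraries 1 to 3 held KLHDC7B at 0.19, 2.21 and 1.05 FPKM, NUPR1 at 6.58, 113.05 and 57.69, and ABCG1 at 0.19, 4.26 and 1.91. In these 3 genes, chosen after their values were seen, library 1 was the lowest of set 1. The shNC libraries held 0.08 to 0.15, 3.9 to 6.62 and 0.24 to 0.39 FPKM. Other named genes ran the other way, such as ANGPTL4 at 11.19, 0.88 and 5.04 and TAGLN at 30.38, 13.85 and 22.52.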
